A study of Mus musculus with 24 samples.

How the data were processed

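Liver RNA of male C57BL/6J mice was measured on Illumina BeadChip arrays, 24 arrays in 6 groups of 4: lean or diet-induced obese mice, each 6 h after sham surgery, 70% hepatectomy or 80% hepatectomy. Groups and replicate numbers come from the labels. The replicate numbers do not pair the arrays of different groups. The arrays lay on 4 slides of 6, and each slide held 2 groups. Only the lean 80% and obese sham groups were spread over a pair of slides, so the first and second slides are linked, as are the third and the fourth, with no link between the pairs.

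The deposited table holds, for 45281 probes, the intensity of each probe on each array, as linear bead averages that the authors did not normalize between arrays. Per the labels, biotin-labelled cRNA was hybridised, and the scanner settings are not given in the sources used here. The same deposited table holds a detection score per probe and array that rises from 0 to 1 with brightness, although the file headers name it a p-value, so 1 minus the score was used as the detection p. The authors' series matrix holds log2 values, which were recomputed here from the deposited intensities by quantile normalization without background correction and centring on each probe's median over arrays. The largest difference from the deposited log2 values was 0.000847.

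Intensities were background-corrected with the normexp model of limma, with the background inferred from the detection p, an offset of 16, quantile normalization and log2. Probes were assigned to genes through the Entrez IDs of the platform table and a RefSeq gene table. Of the probes, 34885 had 1 gene (34807 matched by Entrez ID), 18 had several and 10378 had none. A probe passed when its detection p was under 0.05 on at least 4 arrays. This left 19631 probes, 16500 with 1 gene and 3123 with none. For each gene the probe with the highest mean over all arrays was taken, giving 10765 of the 19057 genes with a probe. Probes with no gene or several genes were not used. The arrays detected 15316 to 17463 probes, with median intensities of 63.5 to 75.4.

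One limma model with a mean for each group was fitted to all 24 arrays, with 18 residual degrees of freedom. The 11 contrasts were each hepatectomy against the sham group of the same diet, obese against lean at each surgery, 80% against 70% in each diet, and both interactions of diet with hepatectomy. The moderated test of limma was two-sided, and p-values were adjusted by the method of Benjamini and Hochberg over all genes of a contrast. A gene with an adjusted p under 0.05 is called changed. With 4 arrays per group, the number of arrays limits the precision. The p-values measure spread between mice as far as each array is another mouse, as the labels have it. Pearson's and Spearman's correlations were computed across genes.

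A gene detected on no array of the lower group has no exact fold change. Its fold is given as at least the ratio of the higher group's mean to the detection floor, the lowest log2 value of a detected probe, 4.73 to 4.92 by array. No fold is given where neither group was detected or that ratio is under 1. Where only some arrays of the lower group detected a gene, the size of its change depends on background as well, and no exact fold is given at 2 arrays or fewer. An interaction of a gene with an undetected group depends on that floor. Beside a list median, the median with such genes at their bound is given where it differs by over 0.1, which held for 15 pairs of list and comparison. The largest such shift was 0.469, for the immediate early genes after obese 80% hepatectomy.

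Of 35 gene lists written before the data were examined, 33 had at least 5 measured members and were tested, and 719 of their 783 members had a probe. The 2 others had 3 measured members each. The set test was fry of limma. Its p asks whether the genes of a set move on balance one way, and its mixed p whether they move in either direction. Neither compares the set with other genes. Adjustment was over the 33 lists of a contrast. By the mixed p 288 of the 363 tests passed. Alternatives were camera with a correlation estimated per list, and fry with slides as random blocks.

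Groups, contrasts, tests, lists and the rule for naming genes were fixed before the data were examined. Named genes are the 10 with the largest rise and the 10 with the largest fall among changed genes whose groups do not overlap (5 each way for interactions), up to 4 changed members of each list that passed or had at least 3 changed members, 21 genes fixed by name, and the genes of results marked for a closer look. Some are left out for length, or because another probe of the gene changed the other way. Mki67 and Cpt1a, fixed by name, are not analysed here. Alb is read by a probe of low brightness.

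Gene and list tests were run on simulated data with the spread of the real arrays, 50 genes per size of change and 10545 unchanged genes. Slide effects and correlated genes are not covered. Of the unchanged genes, 0.0284 to 0.161% were called in the 11 contrasts. Recovery of a log2 change of 0.5 was 64, 46, 56, 50, 50, 64, 38, 52, 56, 18 and 24% in order of the report. A change of 1 was recovered in 86 to 98% for groups and 78 and 74% for interactions, and changes of 2 and 3 in 98% or more. Of 20 unchanged lists, 1 was called in lean 70% against sham, 2 in obese against lean at 70% and 0 elsewhere.

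Slides were examined through the groups that lay on a pair of them. Between the first and second slides limma called 0 genes in obese sham liver (726 at an unadjusted p under 0.05), and between the third and the fourth 168 in lean 80% liver (2057 unadjusted). The correlation within slides was 0.128. Alternatives tried were normexp with an offset of 50, no background correction, upper-quartile scaling, the deposited log2 values, other detection filters, the mean of a gene's probes, slides or replicate numbers as blocks, fits within a slide or to the compared groups alone, a robust trended variance, a 2-fold minimum and leaving out each array. Scaling of lists, the lean 80% arrays of each slide alone, named genes and the macrophage list without 1 array, fixed slide terms for the interaction at 80%, and permuted residuals for the interactions were added after seeing the data. R 4.3.3, limma 3.58.1, the data.table package at version 1.17.8, matplotlib 3.10.9 and numpy 2.4.6 were used.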

Results

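Livers of lean and diet-induced obese male C57BL/6J mice were profiled 6 h after sham surgery or after removal of 70% or 80% of the liver. The question is how the early response to loss of liver mass differs with diet and with the size of the resection. Each of the 6 groups had 4 arrays, and 10765 genes entered the tests. Changes are differences of group means from limma with their standard errors (SE), at n = 4 arrays per group. A bare number in parentheses after a gene is its log2 fold change, given so only where the adjusted p was under 0.05. The p-values measure the spread between arrays labelled as replicates.

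Surgery separated the arrays more than diet. The first principal component held 56.2% of the variance and the second 12.8%. The lowest correlation between arrays of a group, across genes, was 0.977, in the lean 80% group.

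**Figure D1:**
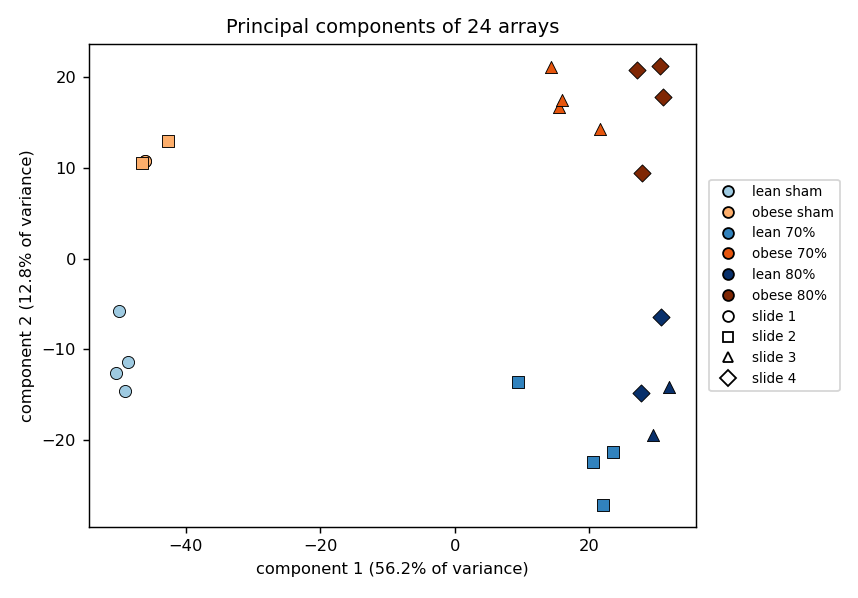
Position of each of the 24 arrays on the first (horizontal, 56.2% of the variance) and second (vertical, 12.8%) principal components of the log2 values. Points are arrays, colours the 6 groups and shapes the 4 slides, and sham arrays lie apart from hepatectomy arrays along the first component.

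In lean mice, 70% hepatectomy changed 5126 genes, 2309 higher and 2817 lower, 1153 of them at least 2-fold (616 higher, 537 lower). The metal-binding protein Mt2 (62.8-fold, log2 5.97, SE 0.23, adjusted p = 9.4e-16) and the insulin-like growth factor binding protein Igfbp1 (55.6-fold, log2 5.80, SE 0.33, adjusted p = 1.8e-12) rose most. Pdk4, which restrains pyruvate oxidation (5.67), the endotoxin co-receptor Cd14 (5.62), the lipid droplet protein Hilpda (5.24), the iron-sequestering Lcn2 (4.93) and Saa3 (4.89) followed. Another lipid droplet protein, Cidec (at least 28.1-fold, adjusted p = 1.9e-12), rose from below detection. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell most (log2 -5.13, adjusted p = 8.8e-07) and was detected on 2 of the 4 lean 70% arrays. It read log2 9.60 on array 1 and 4.39 to 5.04 on the other three, and the change was -6.36 without array 1. No fold is given, since both values depend on the detection floor. The glycogen-targeting phosphatase subunits Ppp1r3b (-4.54) and Ppp1r3c (-4.19), Pnpla3 (-4.48), the insulin-induced Angptl8 (-4.08), the lipogenic regulator Srebf1 (-3.87), Mid1ip1 (-3.82), Nrep (-4.08), Dclk3 (-3.89) and Fam214a (-3.85) fell too.

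Of the immediate early genes, 19 of 23 rose and 0 fell, 4 not passing (19 and 0 adjusted over the list alone, median log2 1.69, 1.46 with bounded members at their bound, fry adjusted p = 2.4e-09, adjusted p = 0.10 with an estimated correlation). Egr1 (4.32), Fos (4.19), Junb (3.15) and Jun (1.64), all transcription factors, were among them. Myc, an inducer of ribosome production, rose (at least 1.12-fold, adjusted p = 0.0063) and was detected on 2 of 4 arrays. Of the ribosome biogenesis genes, 27 of 40 rose and 3 fell, 10 not passing (29 and 3 adjusted over the list alone, median log2 0.51, fry adjusted p = 1.7e-06, adjusted p = 0.20 with an estimated correlation). They included Heatr1 (1.77) and Nop58 (1.52). The G1 cyclin Ccnd1 rose (2.48-fold, log2 1.31, SE 0.20, adjusted p = 8.9e-06). Of the G1/S and DNA replication genes, however, 5 of 25 rose and 9 fell, 11 not passing (5 and 10 adjusted over the list alone, median log2 -0.23, fry adjusted p = 0.013, adjusted p = 0.61 with an estimated correlation). E2f2 (at least 1.90-fold lower, adjusted p = 1.6e-08) and Rrm2 (-1.12) fell. Of the p53 targets, 9 of 15 rose and 2 fell, 4 not passing (9 and 2 adjusted over the list alone, median log2 0.38, fry adjusted p = 2.5e-08, adjusted p = 0.10 with an estimated correlation). Among them was the cell cycle inhibitor Cdkn1a (21.4-fold, log2 4.42, SE 0.28, adjusted p = 1.1e-11).

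Of the acute phase genes, 19 of 26 rose and 3 fell, 4 not passing (19 and 3 adjusted over the list alone, median log2 1.35, fry adjusted p = 2.1e-09, adjusted p = 0.10 with an estimated correlation). Saa1, near the top of the scale in lean sham liver already, did not pass (log2 0.25, SE 0.20, adjusted p = 0.32). Of the IL-6 and STAT3 signalling genes, 11 of 20 rose and 1 fell, 8 not passing (11 and 2 adjusted over the list alone, median log2 0.64, 0.47 with bounded members at their bound, fry adjusted p = 3.0e-10, adjusted p = 0.074 with an estimated correlation). Among them was the feedback inhibitor Socs3 (7.88-fold, log2 2.98, SE 0.25, adjusted p = 1.4e-09). The cytokine Il6 itself was detected on 1 lean 70% array and no lean sham array (adjusted p = 0.11, the lower group below detection). Of the glucocorticoid targets, 9 of 14 rose and 1 fell, 4 not passing (9 and 1 adjusted over the list alone, median log2 0.98, fry adjusted p = 4.6e-14, adjusted p = 0.026 with an estimated correlation). Of the NF-kB and chemokine genes, 7 of 21 rose and 0 fell, 14 not passing (7 and 0 adjusted over the list alone, median log2 0.38, 0.20 with bounded members at their bound, fry adjusted p = 1.6e-05, adjusted p = 0.20 with an estimated correlation). Among them was the neutrophil attractant Cxcl1 (1.99). Beside them the neutrophil markers moved: 6 of 9 rose and 0 fell, 3 not passing (7 and 0 adjusted over the list alone, median log2 0.54, fry adjusted p = 1.2e-05, adjusted p = 0.31 with an estimated correlation). They included S100a8 (4.41) and S100a9 (4.25). Of the Kupffer cell and macrophage markers, 8 of 17 rose and 0 fell, 9 not passing (8 and 0 adjusted over the list alone, median log2 0.52, fry adjusted p = 0.017, adjusted p = 0.56 with an estimated correlation, adjusted p = 0.051 with slides as blocks). Among them was Marco (1.75). The macrophage mean of the fourth lean 70% array, 7.38, lay within the lean sham range, and the other three read 8.29 to 8.75. This call depends on single arrays: 14 members passed without that array, 4 without lean sham 4 or lean 70% array 2 or 3, where fry gave adjusted p = 0.062, 0.072 and 0.063. Of the extracellular matrix and stellate cell genes, 19 of 24 rose and 0 fell, 5 not passing (19 and 0 adjusted over the list alone, median log2 0.69, fry adjusted p = 2.6e-08, adjusted p = 0.10 with an estimated correlation). Examples were Acta2 (3.70) and Ccn2 (3.05).

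Of the fatty acid synthesis genes, 1 of 18 rose and 16 fell, 1 not passing (1 and 16 adjusted over the list alone, median log2 -1.31, fry adjusted p = 1.2e-07, adjusted p = 0.20 with an estimated correlation). Fasn fell (3.54-fold lower, log2 -1.82, SE 0.30, adjusted p = 1.8e-05), and the desaturase gene Scd1 did not pass (log2 0.20, SE 0.20, adjusted p = 0.43). Of the lipid droplet and fatty acid uptake genes, 10 of 19 rose and 1 fell, 8 not passing (10 and 1 adjusted over the list alone, median log2 0.60, fry adjusted p = 2.1e-09, adjusted p = 0.10 with an estimated correlation). Among them was Plin2 (3.28). Of the gluconeogenesis and insulin-repressed genes, 9 of 15 rose and 2 fell, 4 not passing (9 and 3 adjusted over the list alone, median log2 0.80, fry adjusted p = 2.0e-07, adjusted p = 0.23 with an estimated correlation). They included Irs2 (2.43) and Pck1 (1.58). Of the bile acid genes, 2 of 21 rose and 8 fell, 11 not passing (2 and 8 adjusted over the list alone, median log2 -0.30, fry adjusted p = 6.6e-06, adjusted p = 0.31 with an estimated correlation). Cyp8b1 fell (-2.09) and the exporter subunit Slc51b (3.19) rose. Pparg (log2 -0.22, SE 0.20, adjusted p = 0.39) and Lepr (adjusted p = 0.49, the lower group below detection) did not pass, and Cd36 was below detection in both groups.

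Fry passed 28 of the 33 lists, 20 upward and 8 downward. Of all genes tested, 4381 (40.7%) had groups that did not overlap, where chance gives a share of 2.86%. With slides as random blocks 4234 passed, 4227 of them in the same direction, and with slides as fixed terms 2276.

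After 80% hepatectomy in lean mice, 5916 genes changed, 2576 higher and 3340 lower, 1473 at least 2-fold (731 and 742). Pdk4 (113-fold, log2 6.82, SE 0.43, adjusted p = 5.7e-12), Igfbp1 (6.27), Cidec (at least 59.4-fold, adjusted p = 3.7e-14) and Hilpda (5.91) rose most, followed by Cd14 (5.84), Mt2 (5.74), the cholesterol 25-hydroxylase Ch25h (at least 28.2-fold, adjusted p = 1.8e-14), Enc1 (5.25) and the anticoagulant receptor Thbd (5.05). Cyp7a1 was detected on no lean 80% array (at least 75-fold lower, adjusted p = 9.7e-09). Ppp1r3c (-5.29), Ppp1r3b (-5.15), Angptl8 (-4.95), Pnpla3 (-4.83), Tmem25 (-4.22) and Keg1 (-4.01) fell. Ccnd1 did not pass (log2 0.09, SE 0.20, adjusted p = 0.72).

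Among the immediate early genes, 21 of 23 rose and 0 fell, 2 not passing (21 and 0 adjusted over the list alone, median log2 2.29, 2.06 with bounded members at their bound, fry adjusted p = 2.4e-11, adjusted p = 0.040 with an estimated correlation). Fos (5.04) and Jun (2.43) rose, as did Myc, detected on all 4 arrays (at least 1.80-fold, adjusted p = 6.6e-07). Of the IL-6 and STAT3 signalling genes, 12 of 20 rose and 0 fell, 8 not passing (12 and 0 adjusted over the list alone, median log2 1.08, 0.89 with bounded members at their bound, fry adjusted p = 2.0e-12, adjusted p = 0.014 with an estimated correlation). Socs3 rose (3.73), as did Il6, detected on 2 of 4 arrays (adjusted p = 0.038, the lower group below detection). Of the glucocorticoid targets, 10 of 14 rose and 1 fell, 3 not passing (10 and 1 adjusted over the list alone, median log2 1.06, fry adjusted p = 8.5e-15, adjusted p = 0.012 with an estimated correlation). Of the PPARA targets, 16 of 25 rose and 0 fell, 9 not passing (16 and 0 adjusted over the list alone, median log2 0.52, fry adjusted p = 8.9e-05, adjusted p = 0.38 with an estimated correlation). They included Cyp4a14 (adjusted p = 8.55e-05, detected on 2 lean sham arrays) and the thioesterase Acot2 (at least 5.79-fold, adjusted p = 2.8e-08). Of the cholesterol synthesis genes, 0 of 17 rose and 10 fell, 7 not passing (0 and 11 adjusted over the list alone, median log2 -0.82, fry adjusted p = 1.6e-05, adjusted p = 0.41 with an estimated correlation). Among them was Sc5d (-3.48). Cdkn1a (4.88), Lcn2 (3.95), Saa1 (0.57) and Pck1 (1.21) rose and Fasn (-1.86) fell.

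For lean 80%, 24 of 33 lists passed by fry, 16 upward and 8 downward. Groups did not overlap in 4815 genes, 44.73% of those tested (chance share 2.86%), and 5132 passed with slides as random blocks. The lean sham and lean 80% arrays lay on slides that no group links, so slide and surgery cannot be told apart here. The same holds for both resections in obese mice, for diet at 70%, for 80% against 70% in lean mice and for the interaction at 70%.

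**Figure D2:**
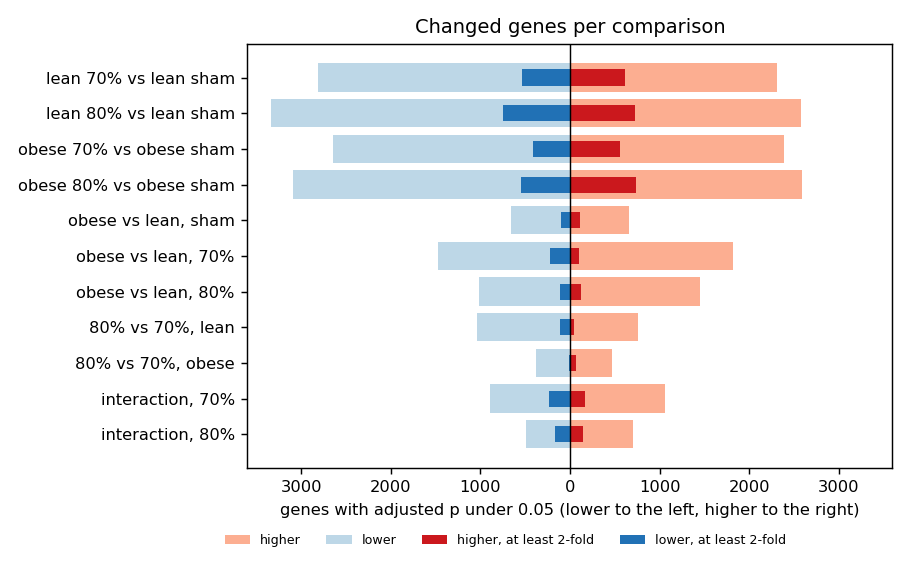
Number of genes (horizontal axis) with an adjusted p under 0.05, higher to the right and lower to the left, in each of the 11 comparisons, with darker bars for changes of at least 2-fold. The counts ran from 846 for 80% against 70% in obese mice to 5916 for lean 80% hepatectomy against sham.

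In obese mice, 70% hepatectomy changed 5039 genes, 2389 higher and 2650 lower, 965 at least 2-fold (554 and 411). The share higher, 47.41%, became 52.18% under upper-quartile scaling. Lcn2 (67.1-fold, log2 6.07, SE 0.49, adjusted p = 6.1e-10), Mt2 (5.77), Cxcl1 (33.6-fold, log2 5.07, SE 0.27, adjusted p = 8.0e-13), Igfbp1 (4.99), Socs3 (28.9-fold, log2 4.85, SE 0.25, adjusted p = 5.3e-13), Fos (4.56), S100a8 (4.36), the TWEAK receptor Tnfrsf12a (4.18) and Saa2 (4.15) rose most. Cyp7a1 fell most (adjusted p = 1.3e-08), from log2 10.86 to 11.82 in obese sham to 4.29 to 4.97, but 3 of the 4 obese 70% arrays were below detection and no fold is given. The lipase inhibitor G0s2 (22.4-fold lower, log2 -4.49, SE 0.28, adjusted p = 6.4e-12), Ppp1r3b (-4.26), Tmem25 (-4.03), Angptl8 (-3.86), Shmt1 (-3.32), Elovl3 (-3.24) and the glucose-6-phosphatase gene G6pc (-3.20) fell too.

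Of the acute phase genes, 22 of 26 rose and 1 fell, 3 not passing (22 and 1 adjusted over the list alone, median log2 1.65, fry adjusted p = 1.1e-10, adjusted p = 0.058 with an estimated correlation). Among them was Saa1 (log2 3.24, adjusted p = 7.3e-12), at the highest value of the scale on 3 of 4 obese 70% arrays, so the scale may limit its size. Of the IL-6 and STAT3 signalling genes, 16 of 20 rose and 0 fell, 4 not passing (16 and 0 adjusted over the list alone, median log2 1.30, fry adjusted p = 3.3e-13, adjusted p = 0.0039 with an estimated correlation), while Il6 was below detection in both groups. Of the glucocorticoid targets, 10 of 14 rose and 2 fell, 2 not passing (10 and 2 adjusted over the list alone, median log2 0.94, fry adjusted p = 2.0e-13, adjusted p = 0.017 with an estimated correlation). Of the unfolded protein and integrated stress response genes, 18 of 25 rose and 2 fell, 5 not passing (19 and 2 adjusted over the list alone, median log2 0.87, fry adjusted p = 2.2e-08, adjusted p = 0.076 with an estimated correlation). They included Chac1 (3.53) and Creld2 (2.35). Of the lipid droplet genes, 8 of 19 rose and 6 fell, 5 not passing (8 and 6 adjusted over the list alone, median log2 0.24, fry adjusted p = 0.026, adjusted p = 0.68 with an estimated correlation). Hilpda (3.55) and Cidec (1.48) rose. Of the amino acid and urea cycle genes, 2 of 25 rose and 8 fell, 15 not passing (2 and 8 adjusted over the list alone, median log2 -0.21, fry adjusted p = 0.0043, adjusted p = 0.62 with an estimated correlation, adjusted p = 0.65 under upper-quartile scaling). Among them was Kynu (-1.45). Jun (1.13), Myc (at least 1.16-fold, adjusted p = 0.0051), Ccnd1 (1.39) and Cdkn1a (1.93) rose, Fasn (-1.04), Pck1 (-0.80) and Pparg (-1.04) fell, and Alb did not pass (log2 -0.18, SE 0.25, adjusted p = 0.59). For obese 70%, 23 lists passed by fry, 13 upward and 10 downward. Groups did not overlap in 4964 genes, 46.11% of those tested (chance share 2.86%), and 4247 passed with slides as random blocks.

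After 80% hepatectomy in obese mice, 5684 genes changed, 2595 higher and 3089 lower, 1284 at least 2-fold (738 and 546). Mt2 (66.8-fold, log2 6.06, SE 0.23, adjusted p = 8.0e-16), the calcium-binding neutrophil proteins S100a8 (61.2-fold, log2 5.93, SE 0.36, adjusted p = 2.7e-12) and S100a9 (at least 45.5-fold, adjusted p = 8.3e-13), Lcn2 (5.79), Ch25h (at least 35.3-fold, adjusted p = 9.9e-15), Cd14 (5.48), Igfbp1 (5.29), Pdk4 (5.19), Socs3 (5.17) and the sphingosine kinase Sphk1 (4.94) rose most. Cyp7a1 fell (adjusted p = 1.6e-08, no fold with 3 of 4 obese 80% arrays below detection). So did Ppp1r3c (-5.36), Ppp1r3b (-5.13), G6pc (-3.96), Elovl3 (-3.90), the succinate receptor Sucnr1 (-3.80) and the replication factor Mcm10 (-3.73).

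Among the NF-kB and chemokine genes, 16 of 21 rose and 0 fell, 5 not passing (16 and 0 adjusted over the list alone, median log2 0.85, fry adjusted p = 4.7e-11, adjusted p = 0.030 with an estimated correlation). Examples were Cxcl1 (4.91), Cxcl2 (at least 8.58-fold, adjusted p = 4.1e-09) and Ccl7 (2.95). Beside them the neutrophil markers moved: 8 of 9 rose and 0 fell, 1 not passing (9 and 0 adjusted over the list alone, median log2 1.87, fry adjusted p = 4.3e-09, adjusted p = 0.18 with an estimated correlation). Of the IL-6 and STAT3 signalling genes, 16 of 20 rose and 0 fell, 4 not passing (16 and 0 adjusted over the list alone, median log2 1.10, fry adjusted p = 3.0e-13, adjusted p = 0.0078 with an estimated correlation). Il6 was detected on 3 of 4 arrays (at least 1.44-fold, adjusted p = 2.3e-05). Of the glucocorticoid targets, 10 of 14 rose and 2 fell, 2 not passing (10 and 3 adjusted over the list alone, median log2 0.85, fry adjusted p = 6.8e-13, adjusted p = 0.038 with an estimated correlation). Of the immediate early genes, 22 of 23 rose and 0 fell, 1 not passing (22 and 0 adjusted over the list alone, median log2 2.18, 1.72 with bounded members at their bound, fry adjusted p = 4.7e-11, adjusted p = 0.038 with an estimated correlation). Of the ribosome biogenesis genes, 34 of 40 rose and 1 fell, 5 not passing (35 and 1 adjusted over the list alone, median log2 1.16, fry adjusted p = 4.2e-11, adjusted p = 0.038 with an estimated correlation). Of the heat shock proteins, 8 of 18 rose and 4 fell, 6 not passing (8 and 5 adjusted over the list alone, median log2 0.21, fry adjusted p = 0.017, adjusted p = 0.74 with an estimated correlation, adjusted p = 0.071 with slides as blocks). Among them was the inducible Hspa1b (2.77). Of the NRF2 and oxidative stress genes, 10 of 18 rose and 0 fell, 8 not passing (10 and 1 adjusted over the list alone, median log2 0.83, fry adjusted p = 1.7e-05, adjusted p = 0.28 with an estimated correlation). They included Srxn1 (3.48). Of the amino acid and urea cycle genes, 3 of 25 rose and 16 fell, 6 not passing (3 and 16 adjusted over the list alone, median log2 -0.49, fry adjusted p = 1.2e-06, adjusted p = 0.28 with an estimated correlation). Among them was Bhmt (-1.77). Myc, detected on 3 of 4 arrays (at least 1.16-fold, adjusted p = 0.0048), Ccnd1 (0.73), Saa1 (3.03), Cidec (2.00) and Cdkn1a (1.89) rose, Fasn (-0.94) fell, and Pck1 did not pass (log2 -0.39, SE 0.22, adjusted p = 0.14). For obese 80%, 23 lists passed by fry, 15 upward and 8 downward. Groups did not overlap in 5533 genes, 51.4% of those tested (chance share 2.86%), and 4951 passed with slides as random blocks.

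The lean and obese responses share no arrays and correlated across genes. At 70%, Pearson's r across genes was 0.754 and Spearman's rho 0.63. There, 1940 genes passed in lean mice alone and 1853 in obese mice alone, while 1370 were higher in both diets against 512.4 if the calls were independent, 1625 lower in both against 693.5, and 191 moved in opposite directions. At 80%, r was 0.838 and rho 0.786, with 1800 higher in both against 621, 2308 lower in both against 958.4, 99 opposite, 1709 in lean mice alone and 1477 in obese mice alone. The slope of the obese on the lean change was 0.688 at 70% and 0.792 at 80%. At 80% both responses set the third and the fourth slides against the first and second, so a shift between these pairs would enter both and raise their correlation. At 70% only the obese response crosses the pairs. Genes are not independent replicates, so no p is given for these values.

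**Figure D3:**
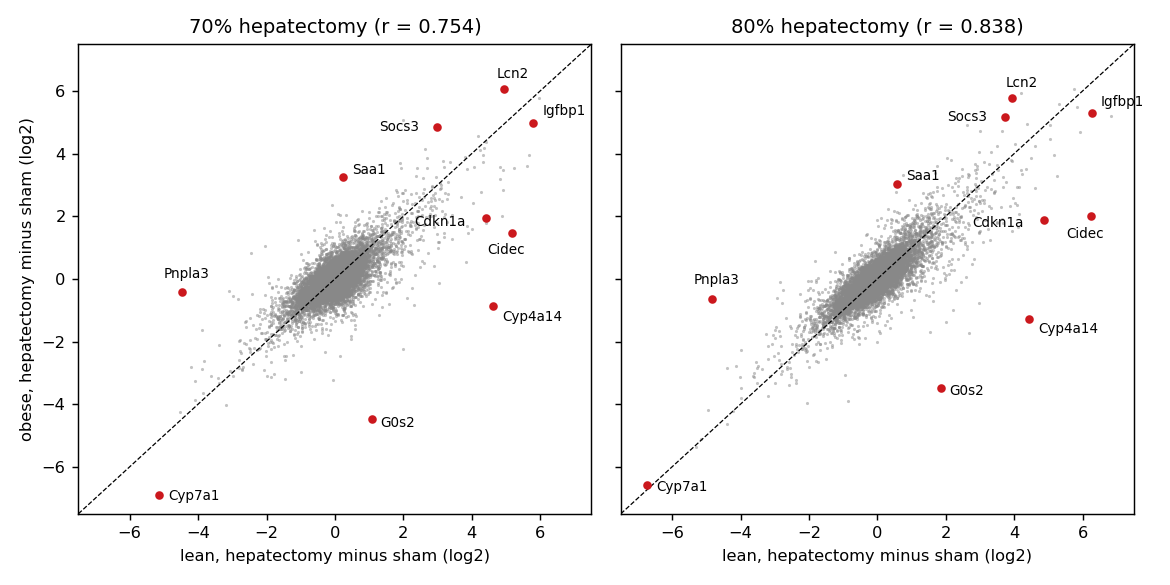
Log2 fold change of each gene after hepatectomy against sham in lean mice (horizontal) and obese mice (vertical), at 70% and at 80%. Grey points are the 10765 genes, red points some of the named genes and the dashed line equal changes, and the correlation across genes was 0.754 at 70% and 0.838 at 80%.

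**Figure D4:**
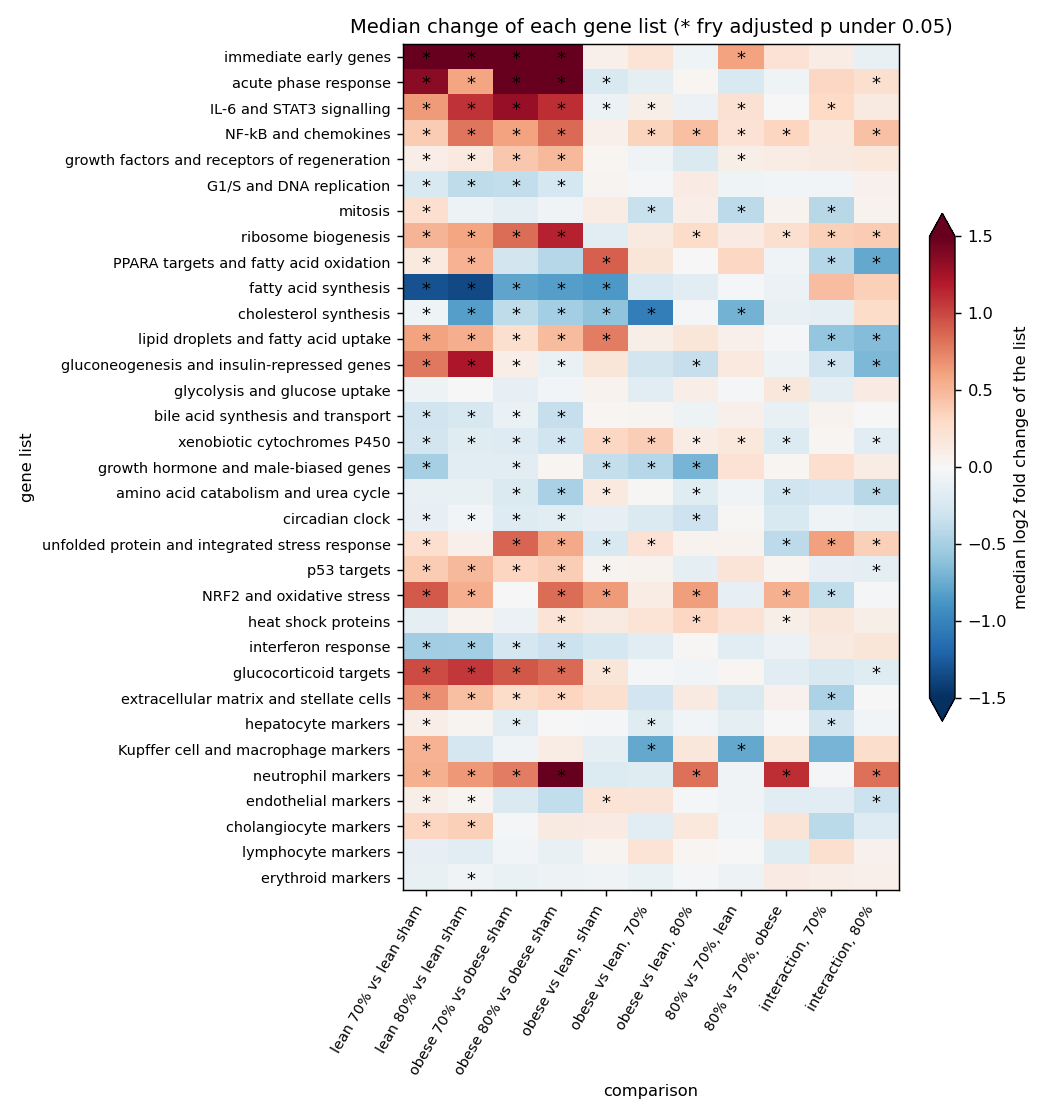
Median log2 fold change of each of the 33 tested gene lists (vertical) in each of the 11 comparisons (horizontal) as colours, with asterisks where fry's adjusted p was under 0.05. The immediate early genes had medians of 1.69, 2.29, 1.89 and 2.18 in the 4 comparisons of hepatectomy with sham.

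Obese and lean sham livers differed in 1313 genes, 657 higher and 656 lower in obese mice, 205 at least 2-fold (109 and 96). Under upper-quartile scaling the share higher went from 50.04 to 47.71%. Cyp4a14 (log2 6.37, SE 0.83, adjusted p = 1.3e-05, detected on 2 of 4 arrays of the lower group), the drug-metabolising Cyp2b9 (at least 47.8-fold, adjusted p = 5.3e-08) and Cyp2b23 (3.62), Cidec (at least 14.5-fold, adjusted p = 2.8e-09) and its relative Cidea (at least 8.36-fold, adjusted p = 3.4e-07), the glutathione transferase Gsta1 (3.59), Acot3 (3.51) and the lipid droplet coat protein Plin4 (8.64-fold, log2 3.11, SE 0.15, adjusted p = 7.4e-13) were higher. Cyp4a14 read log2 10.7 on the fourth lean sham array and 4.37 to 5.25 on the other three. Without that array its log2 change was 7.86, and without the second 5.75. Moxd1 (at least 42.1-fold lower, adjusted p = 3.3e-06), Pnpla3 (24.6-fold lower, log2 -4.62, SE 0.46, adjusted p = 3.2e-07), Tff3 (at least 18.3-fold lower, adjusted p = 5.3e-06), the fatty acid binding protein Fabp5 (at least 11.1-fold lower, adjusted p = 3.4e-06), Hsd3b5 (-3.78), Chrna4 (-3.03) and Saa1 (5.63-fold lower, log2 -2.49, SE 0.20, adjusted p = 2.1e-08) were lower.

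Of the lipid droplet genes, 11 of 19 were higher and 0 lower, 8 not passing (12 and 0 adjusted over the list alone, median log2 0.76, fry adjusted p = 3.2e-08, adjusted p = 0.0076 with an estimated correlation). Of the PPARA targets, 17 of 25 were higher and 0 lower, 8 not passing (20 and 0 adjusted over the list alone, median log2 0.90, fry adjusted p = 1.8e-05, adjusted p = 0.053 with an estimated correlation). The lipogenic receptor gene Pparg was higher (3.06-fold, log2 1.61, SE 0.20, adjusted p = 8.5e-06). Of the xenobiotic cytochromes P450, 12 of 28 were higher and 4 lower, 12 not passing (13 and 4 adjusted over the list alone, median log2 0.31, fry adjusted p = 3.5e-06, adjusted p = 0.042 with an estimated correlation). Among them was Cyp2b10 (3.01). Of the NRF2 genes, 8 of 18 were higher and 0 lower, 10 not passing (11 and 0 adjusted over the list alone, median log2 0.64, fry adjusted p = 0.00050, adjusted p = 0.10 with an estimated correlation). Among them was Gsta2 (2.52). Of the p53 targets, 4 of 15 were higher and 1 lower, 10 not passing (5 and 1 adjusted over the list alone, median log2 0.04, fry adjusted p = 0.0029, adjusted p = 0.28 with an estimated correlation). They included Cdkn1a (7.62-fold, log2 2.93, SE 0.28, adjusted p = 1.7e-07). Of the fatty acid synthesis genes, 1 of 18 were higher and 10 lower, 7 not passing (2 and 11 adjusted over the list alone, median log2 -0.86, fry adjusted p = 0.0039, adjusted p = 0.28 with an estimated correlation). Changed members included Fasn (3.23-fold lower, log2 -1.69, SE 0.30, adjusted p = 0.00037) and Srebf1 (-1.63). Of the cholesterol synthesis genes, 0 of 17 were higher and 8 lower, 9 not passing (0 and 8 adjusted over the list alone, median log2 -0.60, fry adjusted p = 0.010, adjusted p = 0.28 with an estimated correlation). Among them was Sqle (-2.27). Of the acute phase genes, 1 of 26 were higher and 8 lower, 17 not passing (2 and 10 adjusted over the list alone, median log2 -0.23, fry adjusted p = 0.0071, adjusted p = 0.36 with an estimated correlation). Among them was Saa2 (-1.99). Pck1 (1.26) was higher, as was Cd36, detected on 2 of 4 obese arrays (adjusted p = 0.030, the lower group below detection). Socs3 was lower (-1.38), and Ccnd1 (log2 -0.52, SE 0.20, adjusted p = 0.098) and Igfbp1 (log2 0.50, SE 0.33, adjusted p = 0.38) did not pass.

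In sham liver, 14 lists passed by fry, 8 upward and 6 downward. Over all genes, 2150 (19.97%, by chance 2.86%) had groups that did not overlap. With slides as random blocks 1067 passed, with slides as fixed terms 438, within the slide that held both groups 502, and without the third obese sham array 829.

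At 70% hepatectomy, 3293 genes differed between diets, 1816 higher and 1477 lower in obese liver, 322 at least 2-fold. The share higher was 55.15%, and 62.68% under upper-quartile scaling, but of the 322 genes 104 were higher and 218 lower. Cyp2b9 (log2 4.66, SE 0.53, adjusted p = 1.1e-06, detected on 1 of 4 arrays of the lower group), Cyp2b10 (2.78), Cidea (2.62), the BMP-responsive Id1 (2.22), Creld2 (2.12), Cyp2a5 (2.09) and Cxcl1 (4.23-fold, log2 2.08, SE 0.27, adjusted p = 6.5e-06) were higher. Moxd1 (at least 79.6-fold lower, adjusted p = 1.9e-07), Tff3 (-5.21), Fabp5 (-4.12), the neutrophil protease Prtn3 (at least 12.6-fold lower, adjusted p = 3.4e-05), G0s2 (10.6-fold lower, log2 -3.41, SE 0.28, adjusted p = 1.1e-08), Hsd3b5 (-3.33) and Spink1 (-3.15) were lower. Fos (log2 0.45, SE 0.36, adjusted p = 0.35), Socs3 (log2 0.49, SE 0.25, adjusted p = 0.14) and Cdkn1a (log2 0.44, SE 0.28, adjusted p = 0.24) did not pass.

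Of the xenobiotic cytochromes P450, 16 of 28 were higher and 1 lower, 11 not passing (16 and 1 adjusted over the list alone, median log2 0.37, fry adjusted p = 4.0e-08, adjusted p = 0.056 with an estimated correlation). Of the NF-kB and chemokine genes, 8 of 21 were higher and 1 lower, 12 not passing (8 and 1 adjusted over the list alone, median log2 0.33, 0.16 with bounded members at their bound, fry adjusted p = 0.0017, adjusted p = 0.75 with an estimated correlation). They included Ccl4 (1.93). Of the unfolded protein and integrated stress response genes, 10 of 25 were higher and 1 lower, 14 not passing (11 and 1 adjusted over the list alone, median log2 0.22, fry adjusted p = 0.0018, adjusted p = 0.75 with an estimated correlation). Ddit3 (1.97) and Syvn1 (1.76) were higher and Asns (-1.98) lower. Of the Kupffer cell and macrophage markers, 1 of 17 were higher and 11 lower, 5 not passing (1 and 11 adjusted over the list alone, median log2 -0.77, fry adjusted p = 0.015, adjusted p = 0.75 with an estimated correlation, adjusted p = 0.060 with slides as blocks). Changed members included Folr2 (-1.24), Marco (-1.26) and Cd9 (-1.51), and the fourth lean 70% array lay within the obese range. Without lean 70% array 2 or 3 or obese 70% array 4 the call was lost (adjusted p = 0.071, 0.062 and 0.056). Of the cholesterol synthesis genes, 0 of 17 were higher and 11 lower, 6 not passing (0 and 13 adjusted over the list alone, median log2 -1.04, fry adjusted p = 0.0018, adjusted p = 0.73 with an estimated correlation). Among them was Sqle (-2.39). Pck1 (-1.13), Fasn (-0.91) and Scd1 (-0.72) were lower and Pparg (0.79) higher. At 70%, 9 lists passed by fry, 4 upward and 5 downward. Over all genes, 2884 (26.79%, by chance 2.86%) had groups that did not overlap. The groups shared no slide, and 2051 genes passed with slides as random blocks.

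At 80% hepatectomy, 2469 genes differed between diets, 1451 higher and 1018 lower in obese liver, 239 at least 2-fold (124 and 115). Cyp2b9 (at least 21.8-fold, adjusted p = 2.2e-06), Gsta1 (3.46), Gsta2 (3.00), Cidea (2.71), the macrophage elastase Mmp12 (2.70), Hspa1b (2.70) and the lipoprotein receptor Vldlr (2.69) were higher. Moxd1 (-4.70), G0s2 (9.08-fold lower, log2 -3.18, SE 0.28, adjusted p = 2.7e-07), Tff3 (-2.95), Adgrf1 (at least 3.72-fold lower, adjusted p = 2.1e-06), Atp1b1 (-2.19), the activin antagonist Fst (-2.15) and Lamb3 (-2.13) were lower.

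Of the NF-kB and chemokine genes, 11 of 21 were higher and 0 lower, 10 not passing (14 and 1 adjusted over the list alone, median log2 0.45, fry adjusted p = 3.2e-05, adjusted p = 0.16 with an estimated correlation). Among them were Cxcl2 (1.91), Ccl7 (1.46) and Ccl2 (1.41). Beside them the neutrophil markers moved: 4 of 9 were higher and 0 lower, 5 not passing (7 and 0 adjusted over the list alone, median log2 0.82, fry adjusted p = 0.023, adjusted p = 0.70 with an estimated correlation). They included S100a8 (1.34). Of the heat shock proteins, 7 of 18 were higher and 0 lower, 11 not passing (8 and 0 adjusted over the list alone, median log2 0.32, fry adjusted p = 0.0054, adjusted p = 0.68 with an estimated correlation). Among them was Dnajb1 (1.43). Of the gluconeogenesis and insulin-repressed genes, 1 of 15 were higher and 6 lower, 8 not passing (1 and 8 adjusted over the list alone, median log2 -0.34, fry adjusted p = 0.00025, adjusted p = 0.16 with an estimated correlation). Examples were Irs2 (-1.99) and the coactivator Ppargc1a (-1.93). Jun (-0.77) and Myc (-0.71) were lower and Il6, detected on 2 of 4 lean arrays and 3 of 4 obese arrays, higher (adjusted p = 0.010), while Fos (log2 -0.04, SE 0.36, adjusted p = 0.95), Ccnd1 (log2 0.12, SE 0.20, adjusted p = 0.72) and Saa1 (log2 -0.03, SE 0.20, adjusted p = 0.93) did not pass. At 80%, 10 lists passed by fry, 6 upward and 4 downward. Over all genes, 2245 (20.85%, by chance 2.86%) had groups that did not overlap. With slides as random blocks 2100 passed, with slides as fixed terms 1213 and within the slide that held both groups 778.

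In lean mice, 1789 genes differed between 80% and 70% hepatectomy, 756 higher and 1033 lower after the larger resection, 160 at least 2-fold (49 and 111). Which direction prevails depends on the scaling, since the share higher, 42.26%, became 51.96% under upper-quartile scaling. The fasting-induced hormone Fgf21 (3.39-fold, log2 1.76, SE 0.53, adjusted p = 0.026) (not passing without the third lean 80% array, log2 1.008, adjusted p = 0.094), Irs2 (3.19-fold, log2 1.67, SE 0.26, adjusted p = 0.00013), Ch25h (1.51), the iron-regulating hormone Hamp (1.46), Akap12 (1.41), the growth hormone feedback inhibitor Socs2 (1.33) and the phosphatase Ptpn2 (1.30) were higher. Prtn3 (log2 -3.72, SE 0.60, adjusted p = 0.00020, detected on 1 of 4 arrays of the lower group), Saa3 (11.4-fold lower, log2 -3.51, SE 0.47, adjusted p = 2.2e-05), Spink1 (-2.75), Sbspon (at least 4.45-fold lower, adjusted p = 2.5e-09), Bhmt (-2.21), Sqle (-2.02), Milr1 (-1.77) and Ccnd1 (2.33-fold lower, log2 -1.22, SE 0.20, adjusted p = 0.00027) were lower.

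Of the Kupffer cell and macrophage markers, 0 of 17 were higher and 14 lower, 3 not passing (0 and 17 adjusted over the list alone, median log2 -0.77, fry adjusted p = 0.011, adjusted p = 0.40 with an estimated correlation). Among them were Mpeg1 (-1.17), Vsig4 (-1.09) and Marco (-1.11). The list mean was 8.29 to 8.75 on 3 of the lean 70% arrays, but 7.38 on the fourth, within the lean 80% range of 7.27 to 7.60. Without the fourth, all 17 members passed (median -1.09), but without array 2 or 3 only 2 did (medians -0.61 and -0.64, fry adjusted p = 0.043 and 0.044). Of the mitosis genes, 0 of 10 were higher and 3 lower, 7 not passing (0 and 6 adjusted over the list alone, median log2 -0.39, -0.25 with bounded members at their bound, fry adjusted p = 0.0017, adjusted p = 0.40 with an estimated correlation). They included Top2a (at least 1.63-fold lower, adjusted p = 2.1e-09). Of the cholesterol synthesis genes, 0 of 17 were higher and 10 lower, 7 not passing (0 and 11 adjusted over the list alone, median log2 -0.70, fry adjusted p = 0.011, adjusted p = 0.40 with an estimated correlation). Among them was Fdps (-1.52). Of the immediate early genes, 8 of 23 were higher and 0 lower, 15 not passing (14 and 0 adjusted over the list alone, median log2 0.61, fry adjusted p = 0.0047, adjusted p = 0.40 with an estimated correlation). Examples were Atf3 (1.37), Jun (0.79) and Myc. Of the IL-6 and STAT3 signalling genes, 8 of 20 were higher and 1 lower, 11 not passing (10 and 1 adjusted over the list alone, median log2 0.23, fry adjusted p = 0.0017, adjusted p = 0.40 with an estimated correlation). Among them were Bcl3 (1.15) and Socs3 (0.75). In lean mice 8 lists passed by fry, 5 upward and 3 downward. Groups did not overlap in 1358 genes, 12.61% of those tested (chance share 2.86%). With slides as random blocks 799 passed, in a fit of these groups alone 386, with the lean 80% arrays of the fourth slide alone 843, without the third lean 70% array 1132 and without the second lean 80% array 1173.

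In obese mice, 846 genes differed between 80% and 70%, 464 higher and 382 lower, 83 at least 2-fold. The share higher, 54.85%, became 35.84% under upper-quartile scaling, and of the 83 genes 71 were higher and 12 lower. Hspa1b (4.45-fold, log2 2.15, SE 0.42, adjusted p = 0.0033), Cxcl2 (3.65-fold, log2 1.87, SE 0.33, adjusted p = 0.0018), Cd14 (3.64-fold, log2 1.86, SE 0.20, adjusted p = 2.6e-05), Akap12 (1.72), Ch25h (1.70), S100a9 (1.66), Ccl7 (1.60) and S100a8 (1.57) were higher after 80%. Ppp1r3c (5.88-fold lower, log2 -2.56, SE 0.56, adjusted p = 0.0081), Acpp (at least 2.48-fold lower, adjusted p = 0.0018), Eif4ebp3 (-1.26), the clock repressor Ciart (-1.15), Kank1 (-1.12), Aldh8a1 (-1.08), Fgf1 (-1.04) and Ccnd1 (-0.66) were lower.

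Of the neutrophil markers, 6 of 9 were higher and 0 lower, 3 not passing (7 and 0 adjusted over the list alone, median log2 1.10, fry adjusted p = 0.0029, adjusted p = 0.16 with an estimated correlation). NF-kB and chemokine genes moved too: 5 of 21 were higher and 0 lower, 16 not passing (8 and 0 adjusted over the list alone, median log2 0.32, fry adjusted p = 0.00089, adjusted p = 0.11 with an estimated correlation). Of the NRF2 genes, 7 of 18 were higher and 0 lower, 11 not passing (8 and 0 adjusted over the list alone, median log2 0.53, fry adjusted p = 0.0029, adjusted p = 0.16 with an estimated correlation). They included Gclc (1.52). Of the glycolysis and glucose uptake genes, 3 of 12 were higher and 0 lower, 9 not passing (3 and 0 adjusted over the list alone, median log2 0.16, fry adjusted p = 0.0044, adjusted p = 0.25 with an estimated correlation). Among them was Slc2a1 (1.59). Of the unfolded protein and integrated stress response genes, 0 of 25 were higher and 10 lower, 15 not passing (1 and 12 adjusted over the list alone, median log2 -0.39, fry adjusted p = 0.0069, adjusted p = 0.26 with an estimated correlation). Examples were Calr (-0.92) and Creld2 (-0.98). Il6 was higher (at least 1.44-fold, adjusted p = 0.0076). In obese mice 9 lists passed by fry, 6 upward and 3 downward. Groups did not overlap in 1616 genes, 15.01% of those tested (chance share 2.86%). With slides as random blocks 275 passed and with slides as fixed terms 393. Leaving out 1 array gave as few as 308.

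By the interaction test, the response to 70% hepatectomy differed with diet in 1952 genes, 1057 more positive and 895 more negative in obese mice, 402 by at least 2-fold, of which 165 were more positive and 237 more negative. The share more positive, 54.15%, became 66.06% under upper-quartile scaling, which moved the median difference of all genes to 0.103. G0s2 (log2 difference -5.56, SE 0.39, adjusted p = 4.7e-09) rose in lean (1.07) and fell in obese mice (-4.49). Cyp4a14 (log2 difference -5.50, SE 1.18, adjusted p = 0.0025), the thioesterase Acot3 (log2 difference -4.24, SE 0.55, adjusted p = 2.5e-05) and Cidec (log2 difference -3.70, SE 0.42, adjusted p = 8.5e-06) also responded more negatively in obese mice. In lean sham liver Cidec, and on 2 arrays Cyp4a14, lay below detection, so neither size is fixed. Pnpla3 (log2 difference 4.05, SE 0.65, adjusted p = 0.00023), Foxq1 (3.28), Cxcl1 (log2 difference 3.08, SE 0.39, adjusted p = 1.9e-05) and Saa1 (log2 difference 2.99, SE 0.28, adjusted p = 7.5e-07) responded more positively. The Saa1 mean was log2 12.14 in obese sham and 14.63 in lean sham, and 3 of 4 obese 70% arrays lay at the highest value of the scale, 15.42, so both the height of the lean values and the scale limit this difference.

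Of the lipid droplet genes, 1 of 19 responded more positively in obese mice and 7 more negatively, 11 not passing (1 and 7 adjusted over the list alone, median log2 -0.58, fry adjusted p = 6.2e-05, adjusted p = 0.25 with an estimated correlation). Of the gluconeogenesis and insulin-repressed genes, 0 of 15 responded more positively in obese mice and 4 more negatively, 11 not passing (0 and 4 adjusted over the list alone, median log2 -0.30, fry adjusted p = 0.021, adjusted p = 0.41 with an estimated correlation, adjusted p = 0.087 with slides as blocks, adjusted p = 0.081 under upper-quartile scaling). Among them were Pck1 (-2.39, SE 0.31, adjusted p = 2.9e-05) and Ppargc1a (-1.97). Of the unfolded protein and integrated stress response genes, 12 of 25 responded more positively in obese mice and 0 more negatively, 13 not passing (14 and 0 adjusted over the list alone, median log2 0.61, fry adjusted p = 0.00040, adjusted p = 0.37 with an estimated correlation). They included Creld2 (2.44) and Ddit3 (2.15). Of the IL-6 and STAT3 signalling genes, 7 of 20 responded more positively in obese mice and 1 more negatively, 12 not passing (8 and 1 adjusted over the list alone, median log2 0.30, fry adjusted p = 0.0017, adjusted p = 0.41 with an estimated correlation). Among them was Socs3 (1.87, SE 0.36, adjusted p = 0.00099). Cdkn1a responded more negatively (log2 difference -2.49, SE 0.40, adjusted p = 0.00023). Fos (log2 0.37, adjusted p = 0.65), Myc (log2 0.02, adjusted p = 0.96), Ccnd1 (log2 0.08, adjusted p = 0.88), Igfbp1 (log2 -0.81, adjusted p = 0.24), Lcn2 (log2 1.14, adjusted p = 0.26) and Cyp7a1 (log2 -1.76, adjusted p = 0.20) did not pass. At 70%, 10 lists passed by fry, 3 upward and 7 downward, and with slides as random blocks 853 genes passed.

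At 80%, the responses differed in 1188 genes, 701 more positive and 487 more negative in obese mice, 318 by at least 2-fold (151 and 167). Each diet difference in it lies within a linked pair of slides. With slides as fixed terms 398 genes passed, and the share more positive went from 59.01 to 48.99%. Of the genes named here, Hspa1a, Jun and Pparg then did not pass (adjusted p = 0.091, 0.20 and 0.24). G0s2 (log2 difference -5.33, SE 0.39, adjusted p = 1.1e-08), Acot3 (-4.41) and Lamb3 (-3.74, SE 0.33, adjusted p = 2.5e-07) responded more negatively in obese mice. So did Cyp4a14 (-5.71, SE 1.18, adjusted p = 0.0032) and Cidec (-4.25), both limited as at 70%. Pnpla3 (log2 difference 4.20, SE 0.65, adjusted p = 0.00033), Foxq1 (2.75), Hspa1a (log2 difference 2.57, SE 0.56, adjusted p = 0.0046), Saa1 (log2 difference 2.46, SE 0.28, adjusted p = 1.1e-05) and Chrna4 (2.40) responded more positively. The sham differences named at 70% enter the interaction at 80% too. Of the gluconeogenesis and insulin-repressed genes, 0 of 15 responded more positively in obese mice and 6 more negatively, 9 not passing (0 and 7 adjusted over the list alone, median log2 -0.67, fry adjusted p = 0.00038, adjusted p = 0.077 with an estimated correlation). Among them was Irs2 (-2.43, SE 0.37, adjusted p = 0.00025). Of the NF-kB and chemokine genes, 5 of 21 responded more positively in obese mice and 0 more negatively, 16 not passing (8 and 1 adjusted over the list alone, median log2 0.44, fry adjusted p = 0.0036, adjusted p = 0.20 with an estimated correlation). They included Cxcl1 (2.29, SE 0.39, adjusted p = 0.00059). Beside them the neutrophil markers moved: 5 of 9 responded more positively in obese mice and 0 more negatively, 4 not passing (5 and 0 adjusted over the list alone, median log2 0.83, fry adjusted p = 0.022, adjusted p = 0.38 with an estimated correlation). Jun (-1.20), Cdkn1a (-2.98), Pck1 (-1.60) and Pparg (-1.03) responded more negatively and Socs3 (1.45) more positively, and Myc did not pass (log2 -0.67, adjusted p = 0.058). At 80%, 13 lists passed by fry, 5 upward and 8 downward, and with slides as random blocks 913 genes passed.

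Over the 11 comparisons, 171 of 363 list tests by fry passed, and 152 with slides as random blocks. By camera, which compares a list with all other genes, 13 passed with an estimated correlation. Those 13 were the glucocorticoid targets after each hepatectomy, the IL-6 and STAT3 signalling genes after lean 80%, obese 70% and obese 80%, the immediate early genes after lean and obese 80%, the NF-kB and chemokine and the ribosome biogenesis genes after obese 80%, and the lipid droplet genes and cytochromes P450 in obese against lean sham.

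**Figure D5:**
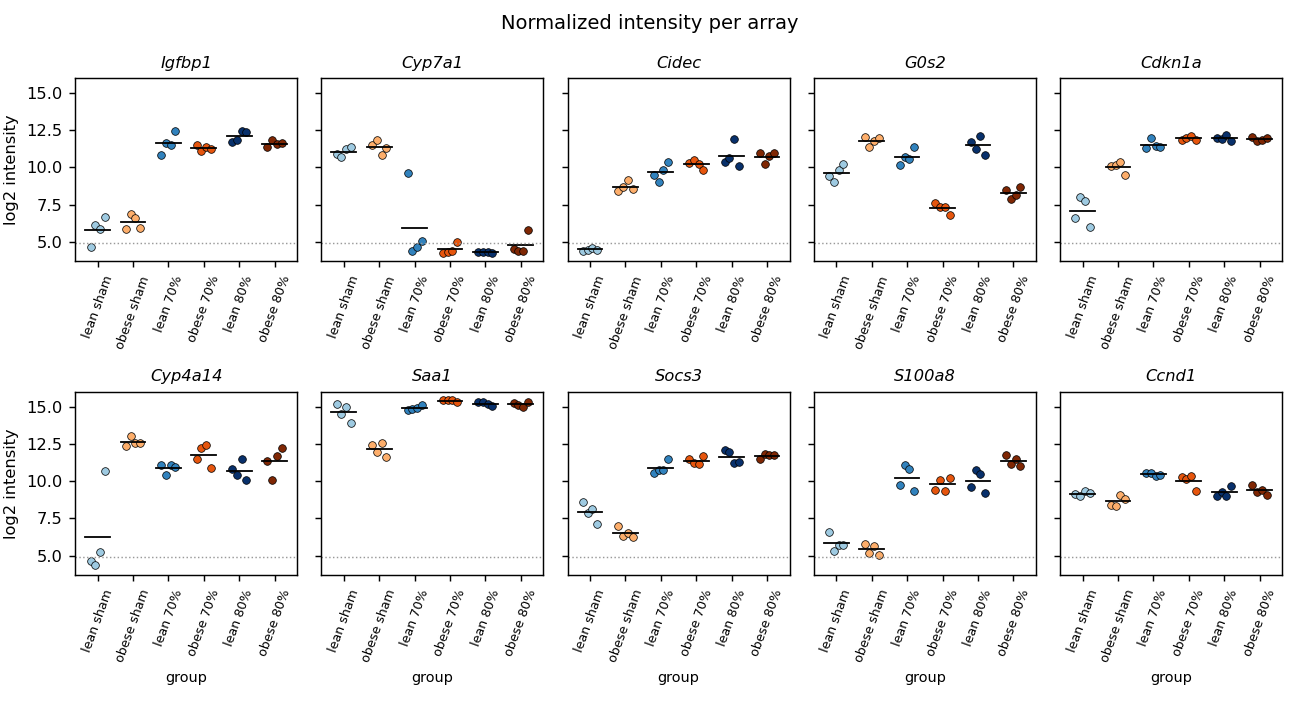
Log2 value on each of the 24 arrays (vertical) for 10 genes, by group (horizontal), points being arrays, lines the group means and dotted lines the detection floor. Igfbp1 was higher in each hepatectomy group than in its sham group, and the Saa1 mean went from 12.14 in obese sham to 15.38 after obese 70% hepatectomy.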

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

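The comparisons with endothelial and erythroid markers, values without 1 array and all counts over other splits of the arrays were chosen after the results were seen. Results stand here because 1 array lay far from the other 3 of its group (its gap over the range of the group above Dixon's critical value), or because the response differed with diet by the interaction test. Chance marks about 1 in 20 groups as having a far array. Of 330 groups of values examined, 25 had one.

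Among genes, the gap over the range was 0.918 for Il6 in obese sham (array 3), 0.91 for Il6 in lean 70% (array 4), 0.912 for Lepr in obese 80% (array 4), 1 for Saa1 in obese 70% (array 4, with the others at the highest value of the scale), 0.957 for Lcn2 in lean 70% (array 4), 0.874 for Cyp7a1 in lean 70% (array 1, log2 9.60 against 4.39 to 5.04), 0.836 for Cyp7a1 in obese 70% (array 4), 0.944 for Cyp7a1 in obese 80% (array 4), 0.891 for Fasn in lean 80% (array 1), 0.83 for Pck1 in obese 80% (array 2) and 0.842 for Alb in obese 70% (array 4). Among list means, it was 0.917 for growth factors in lean 80% (array 3), 0.912 for mitosis in lean sham (array 1), 0.893 and 0.92 for cholesterol synthesis in lean 70% and lean 80% (array 4 in both), 0.931 for gluconeogenesis in obese 80% (array 2), 0.895 and 0.8295 for growth hormone genes in lean sham (array 2) and lean 70% (array 4), 0.872 for amino acid catabolism in lean 70% (array 1), 0.83 for NRF2 genes in lean 70% (array 4), and 0.869 and 0.885 for lymphocyte markers in lean sham (array 4) and obese 70% (array 3). Among array measures, it was 0.89 for probes detected in lean sham (array 2), and 0.87 and 0.888 for the first and second principal components in obese sham (array 3).

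By the interaction test, 1952 genes responded differently with diet at 70% and 1188 at 80%. At 70%, list medians of the difference (obese minus lean) were 0.304 for IL-6 and STAT3 signalling, -0.421 for mitosis, 0.353 for ribosome biogenesis, -0.429 for PPARA targets, -0.580 for lipid droplets, -0.300 for gluconeogenesis, 0.614 for the unfolded protein response, -0.373 for NRF2 genes, -0.477 for extracellular matrix and -0.274 for hepatocyte markers. Under upper-quartile scaling the calls of PPARA targets, gluconeogenesis, NRF2 genes, extracellular matrix and hepatocyte markers were lost, the last with the other direction. Of these 10 calls, 0 held with an estimated correlation and 6 with slides as blocks. Negative gene differences were Acot3 -4.24, Alb -1.19, Cdkn1a -2.49, Cidec -3.70, Cyp4a14 -5.50, G0s2 -5.56, Olig1 -3.28, Pck1 -2.39 and Pparg -0.82. Positive ones were Acpp 3.11 (another probe of which changed the other way), Cxcl1 3.08, Foxq1 3.28, Pnpla3 4.05, Saa1 2.99 and Socs3 1.87.

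At 80%, the list medians were 0.243 for the acute phase response, 0.443 for NF-kB and chemokines, 0.381 for ribosome biogenesis, -0.769 for PPARA targets, -0.645 for lipid droplets, -0.671 for gluconeogenesis, -0.172 for cytochromes P450, -0.421 for amino acid catabolism, 0.359 for the unfolded protein response, -0.146 for p53 targets, -0.179 for glucocorticoid targets, 0.8292 for neutrophil markers and -0.322 for endothelial markers. Under upper-quartile scaling the calls of the acute phase and unfolded protein responses were lost. Of the 13 calls, 0 held with an estimated correlation and 10 with slides as blocks. Negative gene differences were Acot3 -4.41, Cdkn1a -2.98, Cidec -4.25, Cyp4a14 -5.71, G0s2 -5.33, Jun -1.20, Lamb3 -3.74, Pck1 -1.60 and Pparg -1.03. Positive ones were Chrna4 2.40, Foxq1 2.75, Hspa1a 2.57, Pnpla3 4.20, Saa1 2.46 and Socs3 1.45. The sizes for Cidec and Cyp4a14 are not fixed.

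For each of the 9 comparisons of groups, 1 of the 35 splits of the arrays, the real one, gave as many changed genes. The share of 0.0286, the smallest possible with 35 splits, goes against chance as the whole source but does not exclude it. Where the groups differ, the other splits mix them, which widens the spread and lowers their counts. The real and the highest other counts, in fits of the compared groups alone, were 4637 and 0 for lean 70%, 5269 and 0 for lean 80%, 5396 and 1 for obese 70%, 6178 and 0 for obese 80%, 1533 and 0 for diet in sham, 2628 and 0 for diet at 70%, 1648 and 18 for diet at 80%, 386 and 4 for 80% against 70% in lean and 757 and 71 in obese mice. For the interactions, 100 splits were drawn for each, with 1974 and 1922 at 70% and 1248 and 572 at 80%. The splits with 1922 and with 572 genes each exchanged all 4 arrays of the lean hepatectomy group for obese ones but not all lean sham arrays, so they hold part of the difference between diets, a structure of the arrays, and show no chance level. The residuals of a fit without interaction were therefore permuted, which keeps the effects of diet and surgery. In 99 draws each the highest counts were 71 at 70% and 0 at 80%. The share of 0.01, the smallest possible here, goes against chance as the whole source there too. With slides as random blocks, 853 genes passed at 70% and 913 at 80%, and with slides as fixed terms 398 at 80%.

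Macrophage markers were lower after 80% than after 70% hepatectomy in lean mice, with a median of -0.77 over 17 members. It rests on single arrays, since 3 lean 70% arrays had list means of 8.29 to 8.75 and the fourth, 7.38, lay within the lean 80% range of 7.27 to 7.60. Members lower were 14 with all arrays, 17 without the fourth (median -1.09), and 2 without the second or the third. Without the fourth lean 70% array the list also passed in the interaction at 70% (median -0.94, adjusted p = 0.0012), where it otherwise did not (adjusted p = 0.088). A slide effect may produce such a shift, since the groups shared no slide. Obese sham arrays of the second slide differed from those of the first by a median of only -0.0231 (SE over members 0.0651), against 0.523 between lean 70% and lean sham (0.371 with slides as fixed terms). Lean 80% arrays differed between slides by 0.0354 (SE over members 0.0838). An SE over members treats genes as replicates and does not measure the spread between mice. Fewer non-hepatocyte cells of every kind is a possible explanation too, but the endothelial median was -0.0472, above the macrophage median by 0.722 (SE over members 0.0871). That argues against a loss of every kind, not of some. The extracellular matrix and stellate list partly moved with the macrophage list, with a median of -0.219 (fry adjusted p = 0.16) and means of 7.36 to 7.60 on 3 lean 70% arrays, 6.93 on the fourth and 6.98 to 7.10 in lean 80%. A change in macrophage number or state with resection size stays open, as do a change of other cells beside them and a difference between the unlinked pairs of slides.

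Neutrophil markers were higher in obese than in lean mice after 80% hepatectomy, with a median of 0.824 over 9 members. A slide effect could give this, yet within the slide that held both groups the median was 0.972, and 4 of 4 obese arrays lay above both lean arrays of that slide. Over both slides the groups overlap, the second lean 80% array reading 7.37 and the second obese 80% array 7.29. More blood in the obese samples is a possible explanation, but the erythroid median was -0.033, so the neutrophil median exceeded it by 0.857 (SE over members 0.204). Both tests argue against these explanations, but an SE over members does not measure the spread between mice. A difference between diets in neutrophils retained in the liver is a hypothesis, found and tested on the same data, and no cells were counted.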

How the results depend on the processing

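The lean 80% arrays of each slide taken alone, the scaling of each list, named genes and the macrophage list without 1 array, and fixed slide terms for the interaction at 80% were chosen after the data were seen. All 11 comparisons kept genes past the threshold under each alternative run. Their counts stayed within 1.5 times the reported count under other background corrections, upper-quartile scaling, the deposited log2 values, other detection filters, the mean of a gene's probes, robust trended variance and replicate numbers as blocks. The exceptions under the other settings follow, and except where the setting itself uses fewer arrays or a stricter threshold, the cause was not tested.

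Counts with slides as random blocks were 2051 for diet at 70%, 799 for 80% against 70% in lean mice, 275 in obese mice, and 853 for the interaction at 70%. With slides as fixed terms they were 2276 for lean 70%, 438 for diet in sham, 1213 for diet at 80%, 393 for 80% against 70% in obese mice, and 398 for the interaction at 80%, where the share higher went from 59.01 to 48.99%. Within 1 slide they were 502 for diet in sham and 778 for diet at 80%, from fewer arrays. In a fit of the compared groups alone, 80% against 70% in lean mice gave 386. With the lean 80% arrays of the fourth slide alone it gave 843, and with those of the third 2049, while lean 80% against sham gave 5353 and 5152.

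Asking for at least 2-fold gave, in the order of the report, 1153, 1473, 965, 1284, 205, 322, 239, 160, 83, 402 and 318. Upper-quartile scaling kept the counts, but the share higher went from 54.85 to 35.84% for 80% against 70% in obese mice and from 54.15 to 66.06% for the interaction at 70%. The majority also turned for 80% against 70% in lean mice (42.26 to 51.96%), obese 70% (47.41 to 52.18%) and diet in sham (50.04 to 47.71%), and for diet at 70% the share went from 55.15 to 62.68%. With at least 2-fold, the majority turned for diet at 70% (104 higher, 218 lower), lean 70% (616, 537), obese 70% (554, 411), obese 80% (738, 546) and the interactions (165 and 237, 151 and 167).

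Leaving out 1 array gave 829 to 1206 for diet in sham (829 without obese sham 3), 1132 to 2407 for 80% against 70% in lean mice (1132 without lean 70% array 3, 1173 without lean 80% array 2) and 308 to 1088 in obese mice. There, 368, 408 and 318 came without obese 70% arrays 1, 2 and 3, and 509, 337 and 308 without obese 80% arrays 1, 3 and 4. The other 8 comparisons stayed within 1.5 times.

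With replicate numbers as a block, in the order of the report, counts were 5110, 5910, 5022, 5673, 1307, 3309, 2426, 1801, 829, 1941 and 1192. The numbers do not pair samples.

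The correlation of lean and obese responses across genes at 70% was 0.743 with no detection filter. It was 0.769 with normexp offset 50, without background correction, from the deposited log2 values and for genes detected on every array of a group. Leaving out 1 array gave 0.731 to 0.767 at 70% and 0.826 to 0.846 at 80%.

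Of the 171 list calls, 152 held with slides as random blocks. With an estimated correlation 13 held, by camera, which asks another question than fry. Among named genes, values with the other sign, none past the threshold, were Ccnd1 for diet at 80% (-0.00819 with the mean of its probes), Myc for the interaction at 70% (-0.0140 with slides as random blocks), Scd1 for lean 70% (-0.627 with slides as fixed terms), Fos for diet at 80% (0.0598 with random blocks, 0.403 with fixed terms and 0.403 within 1 slide) and Saa1 for diet at 80% (0.0769 with fixed terms and 0.0769 within 1 slide). The macrophage list lost its lean 70% and diet at 70% calls without each of 3 arrays in turn. Leaving out 1 array moved the fold of some named genes by over 1.5 times. Log2 changes became 5.92 for Cyp4a14 in lean 80%, 7.86 for it in diet at sham and -6.98 and -7.20 in the interactions (without lean sham 4), but 3.81, 5.75, -4.88 and -5.09 without lean sham 2. They became -6.36 for Cyp7a1, -5.11 for Ppp1r3c, -5.22 for Ppp1r3b and -4.48 for Fam214a in lean 70% (without lean 70% array 1), and -6.79 for Moxd1 and -5.14 for Tff3 in diet at sham (without lean sham 4). In diet at 70% they were -4.14 for Hsd3b5, -4.75 for Prtn3 and 5.38 for Cyp2b9, and in diet at sham -3.06 for Hsd3b5. For 80% against 70% in lean mice Prtn3 was -4.50, and Fgf21 lost its call (1.008 without lean 80% array 3). Lcn2 was 5.57 in lean 70% and 4.58 in lean 80%. Signal over background limits Cyp7a1, Il6, Myc and Cd36, each undetected in at least 1 group.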

Other observations

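No test in this part was chosen after its result was seen. Some lists of the lean 70% response are given here alone. Of the interferon response genes, 2 of 22 rose and 13 fell, 7 not passing (2 and 13 adjusted over the list alone, median log2 -0.52, fry adjusted p = 6.8e-05, adjusted p = 0.36 with an estimated correlation), with Igtp (-1.72) and Psmb9 (-1.26). Clock genes went both ways: 3 of 14 rose and 5 fell, 6 not passing (3 and 5 adjusted over the list alone, median log2 -0.13, fry adjusted p = 0.0058, adjusted p = 0.63 with an estimated correlation), with Usp2 (-2.71) and Dbp (-1.11). Of the growth hormone and male-biased genes, 1 of 16 rose and 6 fell, 9 not passing (1 and 8 adjusted over the list alone, median log2 -0.49, fry adjusted p = 0.0076, adjusted p = 0.59 with an estimated correlation), with Hsd3b5 (-2.76). Endothelial markers went both ways too: 6 of 16 rose and 4 fell, 6 not passing (6 and 4 adjusted over the list alone, median log2 0.09, fry adjusted p = 0.0074, adjusted p = 0.59 with an estimated correlation), with Lyve1 (2.55) and Dnase1l3 (-0.56). Of the lymphocyte markers, 0 of 7 rose and 1 fell, 6 not passing (0 and 1 adjusted over the list alone, median log2 -0.12, fry adjusted p = 0.080).

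Across genes, the obese against lean sham difference correlated with the lean hepatectomy response at r = 0.249 for 70% and 0.255 for 80%. Both share the lean sham arrays, and with no effect simulated that sharing gave 0.499, with a covariance of 0.0127. The measured covariances were 0.0655 and 0.075, so the correlations alone say little. With the lean sham arrays divided between both comparisons, the 6 divisions gave 0.136 to 0.258 for 70% and 0.179 to 0.233 for 80%, with covariances of 0.0404 to 0.0696. Shared arrays therefore are not the whole source.

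A hypothesis was that genes already shifted in obese sham liver in the direction of the lean response converge between diets after hepatectomy. The prediction was written before the test. Of 257 genes at least 2-fold different in obese sham by 2 of the lean sham arrays, 71 moved the same way after lean 70%, judged by the other lean sham arrays. These kept a median part of 0.0932 of their sham difference at 80% hepatectomy. The 143 genes that did not move kept 0.335 and the 43 that moved the other way 0.324. The difference of 0.242 between the first pair is no test of the hypothesis, since a lean change in the direction of the sham difference itself lowers the kept part. Whether such genes converge stays open.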
